A study of Homo sapiens with 18 samples.

How the data were processed

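CUT&Tag, in which an antibody directs a transposase to chromatin that carries a chosen histone mark, was performed on HL60, a human promyelocytic leukaemia line. Per the labels, doxycycline at 1 µg/ml was given for 5 days to induce a short hairpin RNA (shRNA) against DDX6 (shDDX6) or a control hairpin (shCTRL). The 16 libraries with peak lists cover 4 histone marks, H3K27ac, H3K4me3, H3K27me3 and H3K9me3, with 2 libraries per mark and hairpin. The 2 IgG libraries of the series carry no list used here. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values of tests over libraries measure only the spread between these libraries, which may be technical.

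Per the submitters' processing notes, the tools included BWA 0.7.17-r1188, SAMtools 1.13, deepTools 3.5.1 and MACS2 2.1.0, and the build was hg38. DiffBind, featureCounts and Subread are named there without a role. The authors called broad peaks in each library on its own against a control. Which IgG library served as control for which list, and the calling settings, are not given in the sources used here. In each deposited list, a peak's score is 10 times its −log10 q, truncated to a whole number. The authors' fold enrichment of a peak is its ratio over the local control background. The −log10 p and −log10 q of each peak are deposited beside it, and every listed peak had a −log10 q of at least 1. All folds printed are the authors', and they were used only to describe, rank or filter peaks within a list. Read numbers were not analysed here, so the depth behind each list is unknown and no interval for depth is given.

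Peaks on chromosomes 1 to 22 and X were kept. Overlapping peaks of the 4 libraries of a mark were merged into union regions, and a library held a region when its peaks shared at least 1 bp with it. The gene table (GRCh38.p14, 19970 protein-coding genes) gives neither strand nor transcripts. The planned window around the transcription start site was therefore replaced by windows of 1 kb to each side of both ends of the gene record, here called gene ends. Exons, introns and start sites are not separated, and distances are to the nearest end of a gene record. All coordinates are hg38, counted from 1.

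A region or gene was called shDDX6-only when both shDDX6-labelled libraries held a peak and neither shCTRL-labelled library did, and shCTRL-only in the reverse case. A comparison of 2 against 2 cannot give an exact p below 0.05, so these presence calls carry no p per gene and none could be adjusted over the list alone. Limma, which rests on a model of the spread, was run beside them as an alternative and is given as counts. In the 4 mixed patterns 1 library of each hairpin held a peak and the other 2 did not. Their counts show the spread between libraries. A difference in depth, control or list length between the groups would not raise them, so they are no measure of such a difference. Covered length was compared by a two-sided exact permutation test of the log2 values. The similarity of libraries was measured as the Jaccard index over bp. Its within-group minus between-group mean was set against all 81 splits of the libraries within marks by a one-sided exact permutation test.

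Gene lists were fixed before the data were examined, as were the tests, the rule for named genes and the alternatives not described as added. The 25 lists were granulocyte maturation, monocyte and macrophage, promyelocyte primary granule, stem cell and leukaemia programme, cell cycle and replication, growth arrest and tumour suppression, apoptosis, ribosome biogenesis and MYC targets, P-body and mRNA decay, chromatin regulators, interferon response, inflammatory and NF-kB response, immediate early and AP-1, antigen presentation, developmental transcription factors, erythroid, megakaryocyte, T and NK cell, B cell, stroma and epithelium, housekeeping, HOX clusters, chromosome 19 zinc fingers, olfactory receptors and protocadherin clusters. All list symbols matched the gene table. Members were set against all other protein-coding genes by a two-sided Fisher's exact test. The background for shDDX6-only was the genes with no peak in either shCTRL-labelled library, and for shCTRL-only the genes with a peak in both. The 200 tests were adjusted together by the Benjamini-Hochberg method at 0.05. Genes are the units, so these tests describe the 16 libraries. Neighbouring genes share peaks, so each call was also tested against 10000 circular shifts of gene order, with the share of members as the statistic. A shift test on the hypergeometric tail was added after the first had been seen.

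Overlap of the calls of 2 marks was tested in 24 two-sided Fisher's exact tests with the same adjustment. Expected overlaps of independent lists over all 19970 genes stand beside them. Not every gene could take a call, since shDDX6-only needs no peak in either shCTRL-labelled library. The genes open to a call can overlap between marks, which moves the overlap without a joint change. The same tests on mixed patterns had at most 0.118 genes expected, so they could not pass and are not used. Gene classes were active (H3K4me3 and H3K27ac without H3K27me3), bivalent (H3K4me3 and H3K27me3), H3K27me3 alone and H3K9me3 alone, each from peaks in both libraries of a hairpin. A search for segments without any peak in a set of 8 libraries, which hold peaks in the other 8, was added after the files had been seen.

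Named genes were DDX6 in every library, the 10 genes per mark and call with the highest lower percentile of fold within the 2 lists, up to 6 called members per gene list, mark and call by the same ranking, the HOX clusters, CDKN2A and MYC. For H3K27ac regions more than 2.5 kb from a gene end, the 5 top regions per call were named. Genes named outside this rule are said to have been chosen after their values were seen.

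Alternatives were a −log10 q of at least 3, an equal number of peaks or an equal covered length per library, each library left out, other overlap rules, 5 kb bins and 2.5 kb windows. Limma was run on log2(bp covered within 5 kb of either gene end + 100), without and with a replicate block. Added later were the gene end with more H3K4me3, a crossed replicate block, and the counts without genes in empty segments.

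Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9, with limma 3.58.1 in R 4.3.3. The calling steps were tested on simulated data over 19970 genes, with every library drawn at random from the list of shCTRL H3K27ac replicate 1. The groups thus did not differ in list length as the real ones do. Of 200 genes planted in each direction, 200 and 200 were found, beside 56 and 64 other calls and at most 92 in a mixed pattern. Planted changes were set in every library of a group, so their recovery checks the code alone. In the same simulation 0 of 40 tests of random lists were called, and limma found 200 and 200 planted genes among 12142 tested, with 212 other calls. Peaks on other chromosomes and on unplaced or alternate contigs were left out of all comparisons.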

Results

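CUT&Tag peak lists of 4 histone marks were compared between HL60 libraries labelled shDDX6 and shCTRL, with 2 libraries per mark and hairpin. DDX6 is an RNA helicase of P-bodies, cytoplasmic granules that hold untranslated mRNA, and the series title places the study in myeloid leukaemia. The marks were H3K27ac and H3K4me3, found at active promoters and enhancers, H3K27me3, laid down by Polycomb, and H3K9me3, a mark of heterochromatin. The lists held 32895 to 70377 peaks for H3K27ac, 22627 to 27344 for H3K4me3, 58065 to 65256 for H3K27me3 and 39401 to 65990 for H3K9me3. Peak numbers depend on depth and on the control, neither of which was analysed here.

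DDX6 (chromosome 11, 118747763 to 118791744) held H3K27ac and H3K4me3 at its gene ends in all 8 libraries of these marks, and H3K27me3 and H3K9me3 in 0 of 8. The authors' fold at DDX6 was 5.65 and 5.82 in the shDDX6-labelled H3K27ac lists and 5.88 and 4.93 in the shCTRL-labelled lists. A hairpin acts on mRNA, so a promoter mark at DDX6 does not check the knockdown, and RNA values were not used here. MYC held both active marks in all 8 libraries, with H3K4me3 folds of 24.6 and 18.7 in the shDDX6-labelled and 4.48 and 4.91 in the shCTRL-labelled lists. Folds depend on each list's control and depth, so they are not compared between lists. CDKN2A, which encodes cell cycle inhibitors, held both marks in the 4 shCTRL-labelled libraries and in 0 of the 4 shDDX6-labelled libraries.

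CDKN2A lay in a segment of chromosome 9 (21257605 to 22250845) without any peak of any mark in the 8 shDDX6-labelled libraries. The 8 shCTRL-labelled libraries held 121 peaks there, 24 of H3K27ac, 23 of H3K4me3, 52 of H3K27me3 and 22 of H3K9me3. KLHL9, MTAP, an enzyme of methionine salvage, and CDKN2A held both active marks in the shCTRL-labelled libraries, and the segment also spans CDKN2B and a group of interferon alpha genes. A segment of chromosome X (41848799 to 45177202) was empty in the same 8 libraries and held 106 peaks in the others, among them H3K27ac and H3K4me3 at FUNDC1 and at KDM6A, an H3K27me3 demethylase. The genes of both segments, other than CDKN2A and KDM6A, were chosen after their values were seen. The next segment empty in the shDDX6-labelled libraries held 51 peaks in the others and no gene. Segments empty in the shCTRL-labelled libraries held at most 98 peaks and none had 2 active genes, and the 4 mixed splits of the libraries gave at most 11 peaks. At loci not reported here, 6 of 12 libraries checked did not match their group's labels. Every direction below is therefore stated for libraries as labelled.

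**Figure D1:**
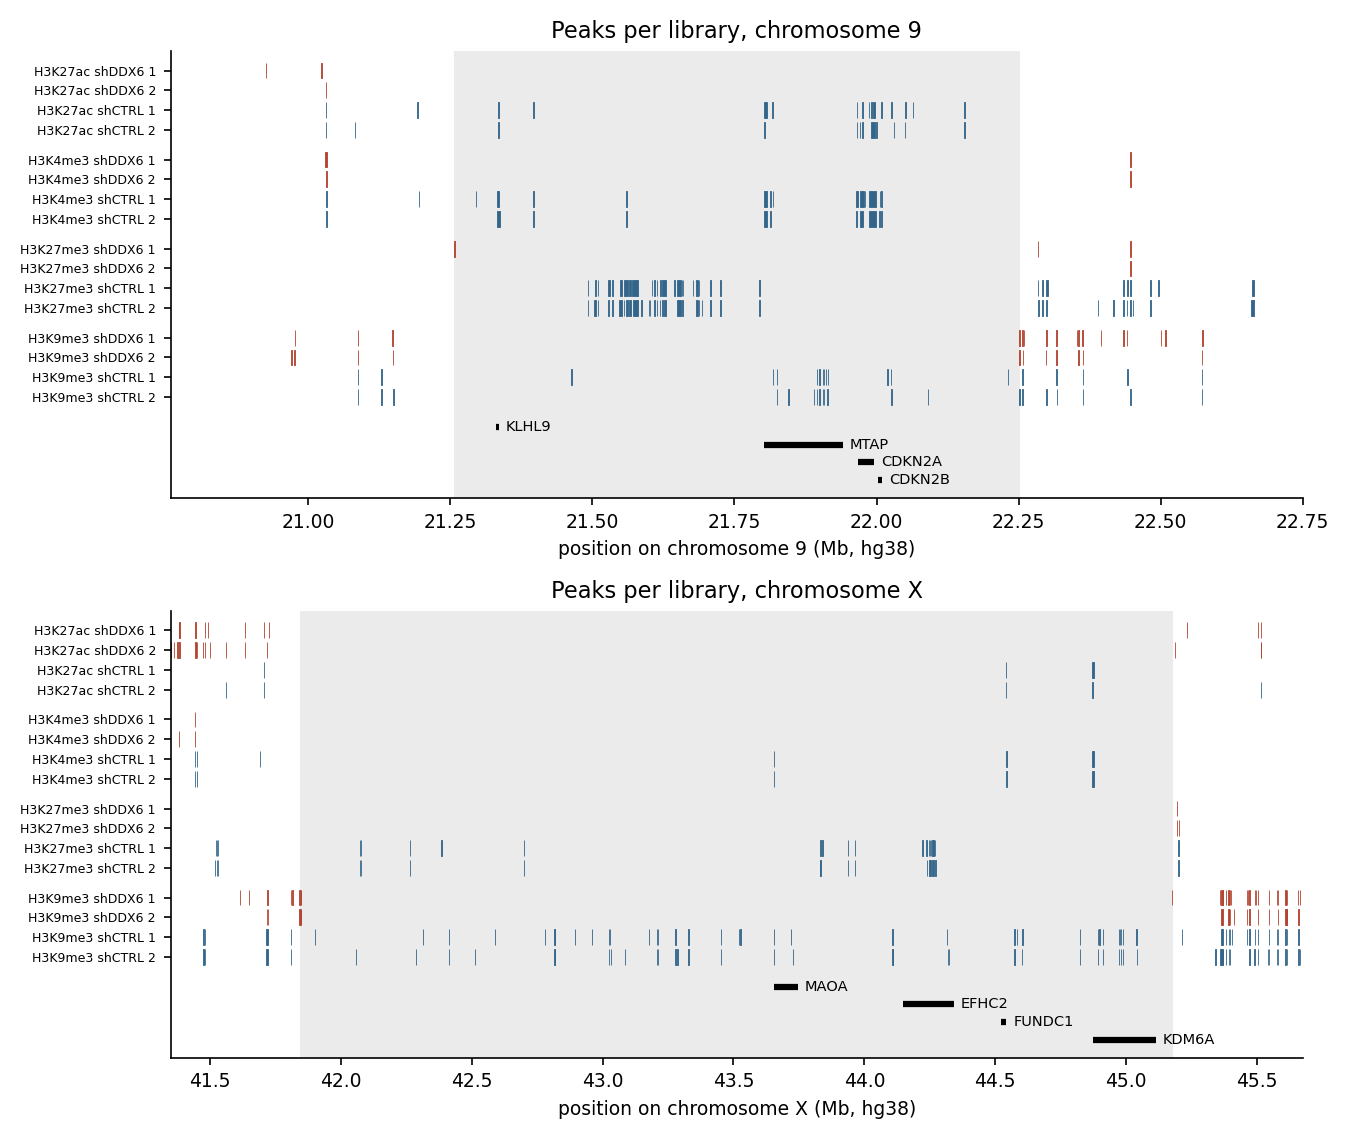
Peaks of the 16 libraries along chromosomes 9 and X (position in Mb, hg38), 1 line per library, with shDDX6-labelled peaks in red, shCTRL-labelled peaks in blue and selected genes in black. The shaded segments held 121 and 106 peaks in the shCTRL-labelled libraries and none in the shDDX6-labelled libraries.

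H3K27ac covered more of the genome in the shDDX6-labelled libraries, 110.5 ± 5.52 Mb against 74.1 ± 12.5 Mb (SD, n = 2 each), a log2 ratio of 0.59. H3K4me3 covered 65.8 ± 7.57 Mb and 77.1 ± 0.797 Mb, and H3K27me3 202 ± 6.48 Mb and 221.2 ± 0.757 Mb, in the shDDX6- and shCTRL-labelled libraries. In these 3 marks the 2 groups did not overlap. H3K9me3 covered 106.1 ± 30.6 Mb and 115.7 ± 6.1 Mb, a difference smaller than the spread between the shDDX6-labelled libraries. The exact permutation p was the smallest that 2 against 2 allow for the first 3 marks, which is above 0.05, and 1 for H3K9me3.

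H3K27me3 separated the groups more than any other mark. Its Jaccard index was 0.655 within the shDDX6-labelled pair and 0.677 within the shCTRL-labelled pair, against 0.222 to 0.231 between groups. The within-group values were 0.394 and 0.514 for H3K27ac, 0.695 and 0.752 for H3K4me3, and 0.507 and 0.574 for H3K9me3. Between groups they were 0.277 to 0.301, 0.521 to 0.544, and 0.336 to 0.37. Averaged over the 4 marks, the index was 0.246 higher within than between groups, and 1 of 81 splits, the real one, gave a value as large (one-sided exact permutation p = 0.0123). Each mark was split on its own, so this p assumes that libraries of different marks are independent, which the labels do not settle.

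**Figure D2:**
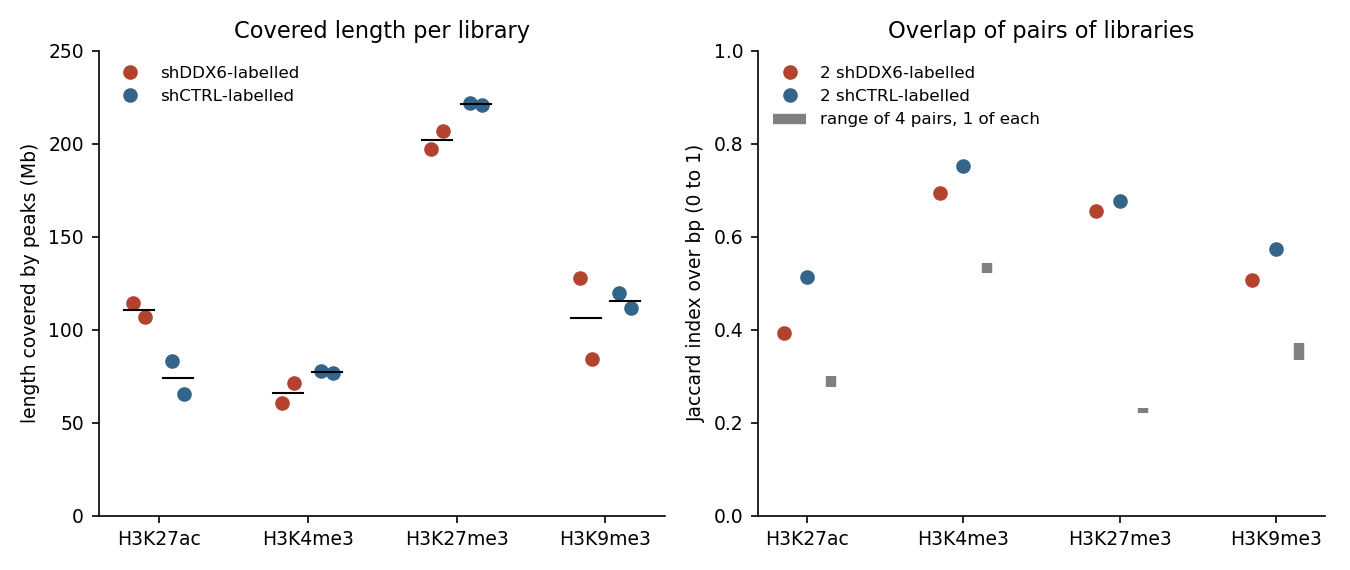
Left, length covered by peaks per library (Mb), with a line at each mean of 2 libraries. Right, Jaccard index of pairs of libraries over bp, where the grey bar spans the 4 pairs of 1 shDDX6- and 1 shCTRL-labelled library; in each mark both within-group values lie above it, most of all for H3K27me3 (0.655 and 0.677 against at most 0.231).

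Members of 3 lists, granulocyte, monocyte and interferon, held shDDX6-only H3K27ac more often than other eligible genes did. ITGB2 and ITGAM, which form a leukocyte integrin, CAMP, an antimicrobial peptide, S100A12, NCF4 and FPR1 led the shDDX6-only calls at 7 of 13 eligible granulocyte maturation genes against 15.1% of other genes (adjusted p = 0.0156, log2 odds ratio 2.70). Of the monocyte and macrophage genes 8 of 17 were shDDX6-only (adjusted p = 0.0182), among them MS4A7, EGR2, ITGAX and the monocyte transcription factors IRF8 (fold 3.44 and 4.03) and KLF4. Of the interferon response genes 10 of 23 were shDDX6-only, led by XAF1, MX2, GBP2, OAS1, OASL and IFIT2 (adjusted p = 0.0139). Other marks did not follow in all 3 lists. In the same order, shDDX6-only H3K4me3 was found at 1 of 13, 3 of 12 and 4 of 14 eligible genes, against 16.95%, 16.92% and 16.91% of other genes. Of members called for H3K27me3, a repressive mark, 3 of 4, 2 of 2 and 0 of 9 were shDDX6-only. None of these passed the threshold. The shDDX6-labelled H3K27ac libraries behind these calls are among the 8 without any peak at CDKN2A and KDM6A. With gene order shifted, the 3 lists kept adjusted p of 0.0306, 0.0492 and 0.0432. The calls ended when shDDX6-only was set against shCTRL-only: 7 of 8, 8 of 9 and 10 of 10 called members were shDDX6-only, against 86% of other called genes in each case (adjusted p = 1 for each). All 3 calls ended without shDDX6 replicate 1 (adjusted p = 0.329, 0.185 and 0.363), the granulocyte call also without shCTRL replicate 1 (0.0905) or 2 (0.0506) and at equal covered length (0.771), and the monocyte call without shDDX6 replicate 2 (0.0646) or shCTRL replicate 1 (0.0626). With a −log10 q of at least 3 the granulocyte and interferon p were 1, with 2.5 kb windows the monocyte and interferon p were 0.0749 and 0.12, and at the gene end with more H3K4me3 the monocyte p was 0.0661.

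IL7R, LCK and CD7 were shCTRL-only for H3K27ac, 3 of 5 T and NK cell genes with H3K27ac in both shCTRL-labelled libraries, against 2.28% of other genes (adjusted p = 0.00181), a call that ended with peaks of −log10 q of at least 3 (adjusted p = 1) and when set against shDDX6-only calls (adjusted p = 0.0894). B cell genes were shCTRL-only in 1 of 8 cases (adjusted p = 0.723). Chromosome 19 zinc finger genes were shCTRL-only in 8 of 114 cases (adjusted p = 0.0462, 0.14 with gene order shifted), and OR9A4, OR52K1 and OR6B2 were 3 of 3 olfactory receptor genes (adjusted p = 0.000222, 0.0503 at equal covered length, and 1 with a −log10 q of at least 3). Olfactory receptor genes were rarely shDDX6-only, 6 of 388 (adjusted p = 1.15e-18). Protocadherin genes were shDDX6-only in 21 of 52 cases (adjusted p = 0.000173), but the p was 0.45 with gene order shifted, 0.204 without shDDX6 replicate 1 and 0.727 with a −log10 q of at least 3, and the direction turned with 2.5 kb windows (log2 odds ratio −3.76).

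Over all gene ends, H3K27ac was shDDX6-only at 1388 genes and shCTRL-only at 225, against 16 to 150 genes in the mixed patterns. The strongest shDDX6-only genes were EHBP1 (chromosome 2, 62673878 to 63046487, fold 7.68 and 10.2 in replicates 1 and 2), IGF2BP2, an mRNA-binding protein gene (fold 7.46 and 10.0), FOXD4, LOC124905135, ZNF521, SCP2, ANKRD18B, TMEM263, BHLHE22 and LOC124900252. The strongest shCTRL-only genes were PROK2 (chromosome 3, 71771655 to 71785148, fold 6.47 and 5.63), KDM6A, CDKN2A, ITM2A, RAVER2, PALS2, NEDD1, ZNF382, ZNF529 and SLC35G1. The balance of 86.1% shDDX6-only changed with the peaks kept: it was 59% (808 and 562 genes) with an equal number of peaks, 45% (599 and 732) at equal covered length and 35.7% (474 and 853) with a −log10 q of at least 3. Without shDDX6 replicate 1 there were 2361 shDDX6-only genes, and without shDDX6 replicate 2 there were 569 shCTRL-only genes.

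Most of the called H3K27ac regions lay away from gene ends. The share over all union regions was not computed, so the shares below cannot be read as particular to the calls. Of 108419 union regions, 12741 were shDDX6-only and 3891 shCTRL-only, against 650 to 1811 in the mixed patterns, and 79.2% and 87.2% of them were more than 2.5 kb from any gene end. The strongest distal shDDX6-only regions lay inside RAB11FIP3 (chromosome 16, 491752 to 494041), THSD7A (chromosome 7, 11631953 to 11639714), CD109 (chromosome 6, 73694633 to 73699865) and PPM1L (chromosome 3, 160799967 to 160802575), and between genes on chromosome 17 (20833703 to 20844706), 93860 bp from LOC124900389. The strongest distal shCTRL-only region (chromosome 12, 69328892 to 69333083, fold 6.84 and 5.93) lay 15298 bp from the end of LYZ, the gene of the myeloid enzyme lysozyme. The others lay inside IGSF10 and SLC8A1 and nearest to SERPINB8 and RPL21. This balance turned at equal covered length, with 2494 shDDX6-only and 5350 shCTRL-only regions, with an equal number of peaks (4258 and 5710), with a −log10 q of at least 3 (1228 and 1618) and without shCTRL replicate 2 (14056 and 14916).

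H3K4me3 was shDDX6-only at developmental genes. Of developmental transcription factor genes with no H3K4me3 in the shCTRL-labelled libraries, 40 of 86 were shDDX6-only against 16.6% of other genes (adjusted p = 5.73e-09, log2 odds ratio 2.13), among them MSX1 (fold 22.4 and 13.1), ALX4, FOXF1 and FOXC1. HOX genes, which set position along the body axis, were shDDX6-only in 14 of 24 cases (adjusted p = 0.00012). They were HOXB2, HOXB4 to HOXB9 and HOXB13 in the HOXB cluster, HOXC8 to HOXC11, HOXD8 and HOXD11. The HOX call rests on few loci, with p of 0.0678 after shifting gene order, while the developmental list kept 0.0019, the smallest value given by 10000 shifts. With the hypergeometric tail as the shift statistic, added later, the adjusted HOX p was 0.008, so this call depends on the statistic. Protocadherin genes were shDDX6-only in 24 of 51 cases (adjusted p = 1.55e-05, 0.221 with gene order shifted and 0.024 with the tail statistic) and olfactory receptors in 1 of 387 (adjusted p = 1.21e-28).

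Zinc finger genes of chromosome 19 were over-represented among the shCTRL-only H3K4me3 calls. Of 175 with H3K4me3 in both shCTRL-labelled libraries, 13 were shCTRL-only, among them ZNF382, ZNF529, ZNF607, ZNF667, ZNF714 and ZNF461, 7.43% against 2.04% of other genes (adjusted p = 0.00152). This was the single list that also differed in the balance of the 2 calls, with 11 of 24 called members shDDX6-only against 84.4% of other called genes (adjusted p = 0.00183). Olfactory receptors were shCTRL-only in 2 of 3 cases (adjusted p = 0.0156, but 1 at equal covered length or with 2.5 kb windows and 0.198 with a −log10 q of at least 3). MPO, the myeloperoxidase gene of promyelocyte granules (chromosome 17, 58269855 to 58280935), held H3K4me3 in the shCTRL-labelled libraries alone (fold 15.8 and 15.8), while H3K27ac was present in all 4. EIF4ENIF1, whose product is a P-body partner of DDX6, showed the same H3K4me3 pattern (fold 11.9 and 12.2).

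Over all gene ends, 1299 genes were shDDX6-only and 251 shCTRL-only for H3K4me3, against 3 to 20 in the mixed patterns. The strongest shDDX6-only genes were SLC35F1 (chromosome 6, 117907264 to 118317671, fold 28.0 and 17.9), FOXD4L1, EPAS1, a hypoxia-inducible transcription factor gene, GCNT4, TCHH, PLPP3, PRXL2A, MYO1E, TMEM9 and OTP. The strongest shCTRL-only genes were ZNF382, ZNF529, LOC124900173, MPO, LOC124904409, GEMIN4, KDM6A, CDKN2A, ZNF607 and ZNF667. Of 35447 regions, 4451 were shDDX6-only and 2988 shCTRL-only, against 97 to 274, and this balance turned with 5 kb bins (951 and 2974) and without shCTRL replicate 1 (5068 and 6335) or 2 (4864 and 5733). The gene-end balance of 83.8% was 96.2% at equal covered length (2179 and 87 genes) and turned to 43.2% with limma on covered bp (1933 higher and 2546 lower genes, adjusted p under 0.05). It did not turn in limma with a replicate block (1526 and 906) or a crossed block (1735 and 1325), and the labels do not say that libraries are paired. Limma made more false calls in the simulation than its threshold allows, so these counts are descriptive.

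**Figure D3:**
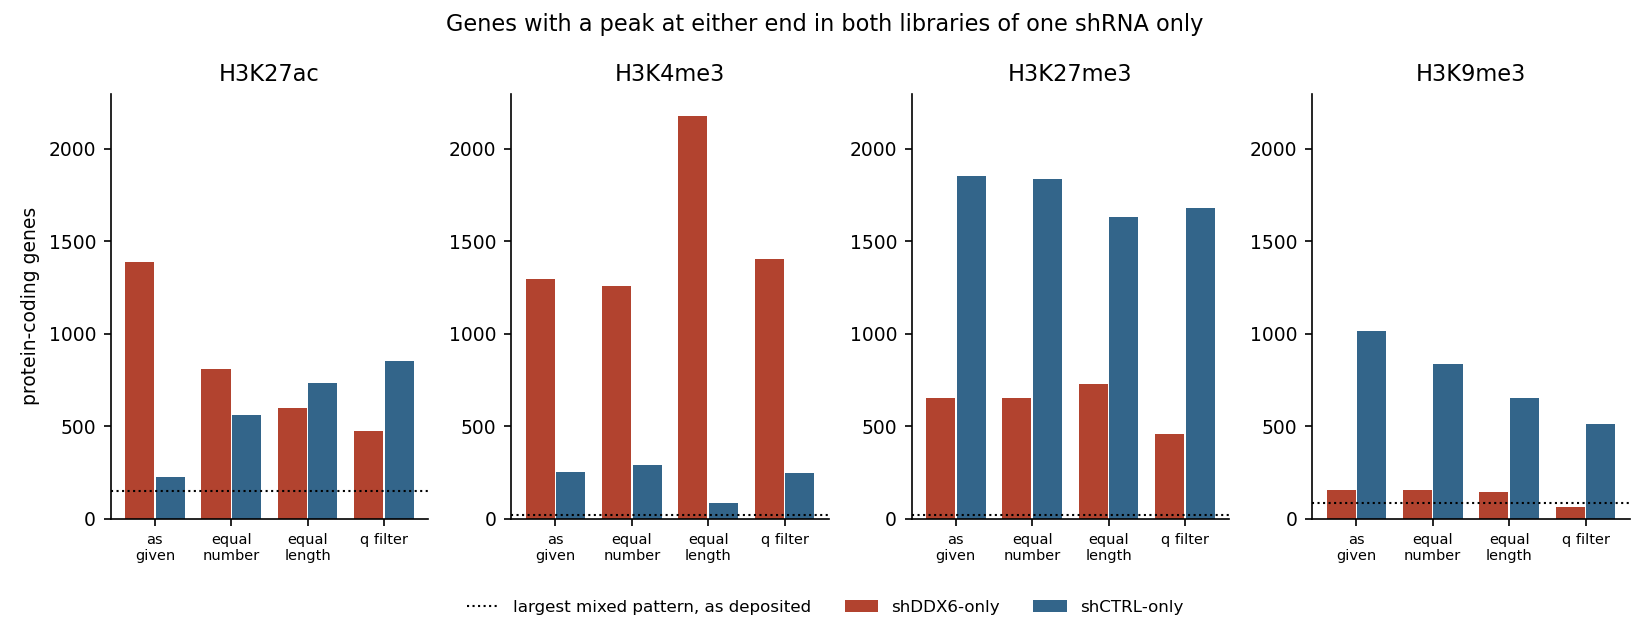
Protein-coding genes (number) with a peak at either gene end in both shDDX6-labelled libraries and neither shCTRL-labelled one (red), or the reverse (blue), for each mark under 4 settings; the dotted line is the largest mixed pattern with the lists as deposited. The H3K27ac balance turned from 1388 and 225 genes to 599 and 732 at equal covered length, while H3K27me3 and H3K9me3 kept more shCTRL-only genes in each setting shown.

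H3K27me3 was more often shCTRL-only, at 1851 genes against 654 shDDX6-only genes, with 4 to 19 in the mixed patterns. The strongest shCTRL-only genes were SEC14L2 (chromosome 22, 30397018 to 30425303, fold 11.1 and 12.7), HEG1, PRAC1, the homeobox gene UNCX, FOXL2, FOXL2NB, NCS1 and the metallothionein genes MT1B, MT1E and MT1F. The strongest shDDX6-only genes were SIM2 (chromosome 21, 36699115 to 36749917, fold 6.69 and 7.75), LOC124903828, OLFM1, INS-IGF2, ADGRA1, BMPR1B, AKAP12, PRDM16, GPR37 and KIF26A. Of 100306 regions, 21068 were shCTRL-only and 17936 shDDX6-only, against 281 to 511 in the mixed patterns. The balance of regions turned at equal covered length, with 13479 shCTRL-only and 18959 shDDX6-only, and without shDDX6 replicate 1 (22707 and 31203) or 2 (23024 and 31157).

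Developmental transcription factor genes kept H3K27me3 more than other genes, and some had it in the shDDX6-labelled libraries alone. MSX1, PAX6, IRX4, FOXC2, SOX9 and IRX2 led the shDDX6-only calls at 9 of 30 eligible genes against 4.22% (adjusted p = 7.1e-05). Of the 83 with H3K27me3 in both shCTRL-labelled libraries, 16 were shCTRL-only, 19.3% against 46.9% of other genes (adjusted p = 9.94e-06), and so were 7 of 35 HOX genes (adjusted p = 0.0182). With gene order shifted these p were 0.05 and 0.45, and the HOX value was 0.157 without shDDX6 replicate 1, 0.334 with a −log10 q of at least 3 and 0.524 at the gene end with more H3K4me3. Chromosome 19 zinc finger genes were shDDX6-only in 1 of 236 cases (adjusted p = 0.0124, and 0.166 with a −log10 q of at least 3). Interferon genes were shCTRL-only in 9 of 11 cases, led by ISG20, IFIT2, IFIT5 and CMPK2, and did not pass the threshold (adjusted p = 0.245).

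H3K9me3 was shCTRL-only at 1015 genes and shDDX6-only at 155, with 4 to 84 in the mixed patterns. Chromosome 19 zinc finger genes, whose bodies carry H3K9me3 in many cell types, kept it: 0 of 212 were shCTRL-only against 48% of other genes (adjusted p = 1.41e-54). Of all 240 members of the list, 210 held it in both shDDX6-labelled libraries, 1 of them as a shDDX6-only gene. Of 51 protocadherin genes 0 were shCTRL-only (adjusted p = 7.15e-12). HOX genes were shCTRL-only in 12 of 14 cases, among them HOXA5, HOXA6, HOXA7, HOXA9, HOXA10, HOXA11 and HOXA13 (adjusted p = 0.0182, but 0.413 with gene order shifted 0.0506 without shCTRL replicate 2, 0.0513 with 2.5 kb windows and 0.455 with a −log10 q of at least 3). The strongest shCTRL-only genes were WDR89 (chromosome 14, 63597039 to 63641871, fold 7.69 and 7.48), PPP1R42, TCF24, SDC3, TLE1, EBF3, EPHA6, DCLK2, NWD1 and F7, and the strongest shDDX6-only genes were ZNF334 (chromosome 20, 46462313 to 46513559, fold 7.01 and 6.67), ZNF778, GIN1, NDFIP2, GTF3C3, LRTM3, GSTA5, OR10H3, STK17B and SLC6A16. Of 102031 regions, 11848 were shCTRL-only and 7540 shDDX6-only, against 273 to 2040, and this balance turned at equal covered length (5079 and 6874) and without shDDX6 replicate 2 (12579 and 29592). Without shDDX6 replicate 2, which had the shortest list, 651 genes were shDDX6-only.

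**Figure D4:**
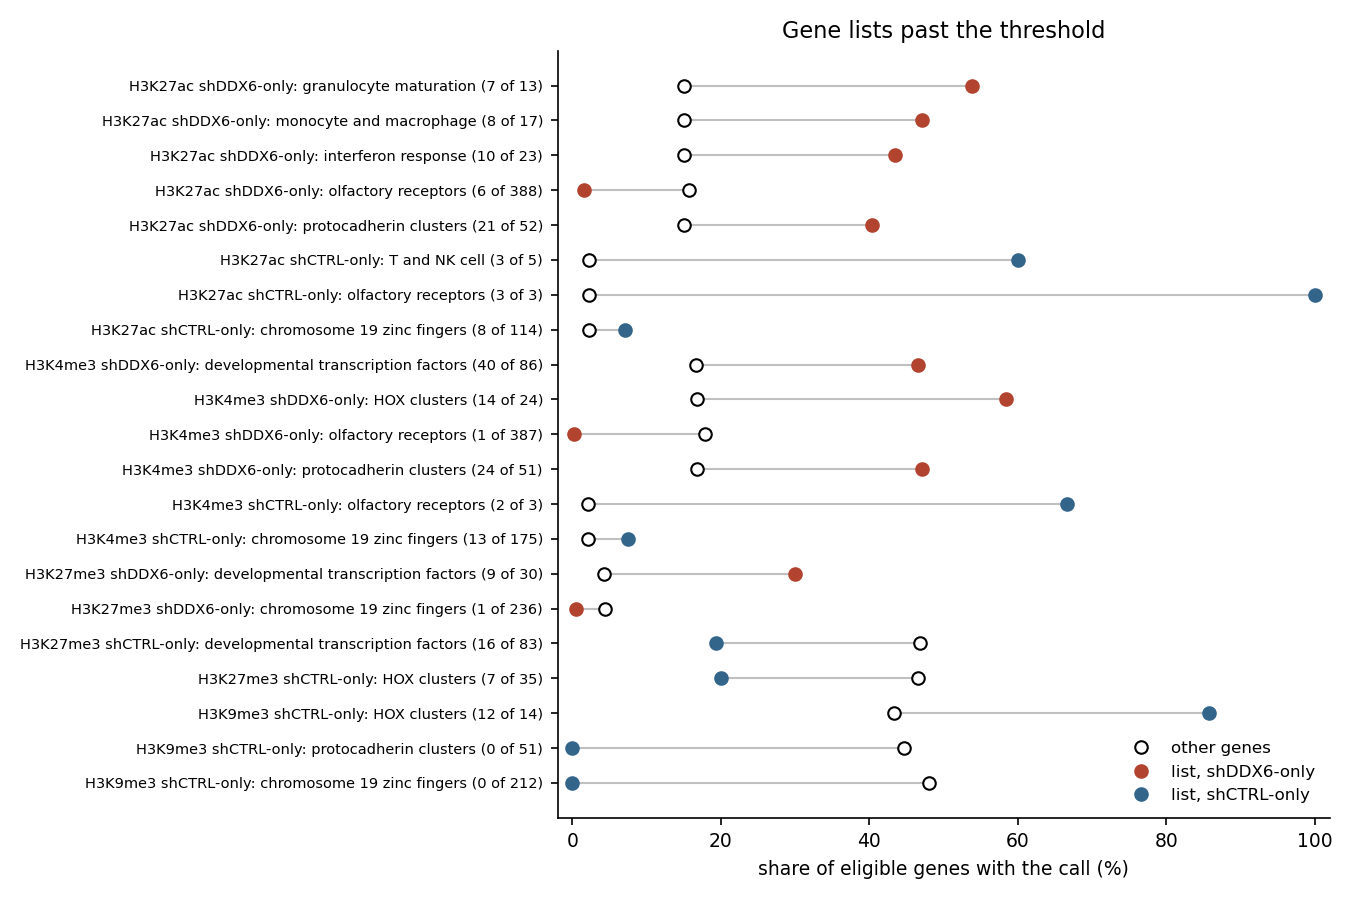
Share of eligible genes with a call (%) for the 21 list tests past an adjusted p of 0.05, in list members (filled, red for shDDX6-only and blue for shCTRL-only) and in other genes (open). Members stood above other genes in 14 tests, such as H3K4me3 at developmental transcription factors (40 of 86), and below in 7, such as H3K9me3 at chromosome 19 zinc fingers (0 of 212).

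In total 21 of 200 list tests passed, 15 of them also with gene order shifted by the share of members, 1 of these with a p that rounds to 0.05. By the hypergeometric tail, the shift statistic added later, 17 passed, and these were not the same set with more added. Setting shDDX6-only against shCTRL-only calls left a single passing list, the chromosome 19 zinc fingers for H3K4me3. Lists with no call for any mark were promyelocyte primary granule, stem cell and leukaemia programme, cell cycle and replication, growth arrest and tumour suppression, apoptosis, ribosome biogenesis and MYC targets, P-body and mRNA decay, chromatin regulators, inflammatory and NF-kB response, immediate early and AP-1, antigen presentation, erythroid, megakaryocyte, B cell, stroma and epithelium, and housekeeping. Single members still differed. CD74 and HLA-DRB1, of the class II antigen presentation pathway, were shDDX6-only for both H3K27ac (fold 3.26 and 3.53 at CD74) and H3K4me3. KIT, a stem cell factor receptor gene, was shCTRL-only for H3K27ac, and HOXA10 was shDDX6-only for it. All 29 ribosome biogenesis and MYC target genes held H3K27ac and H3K4me3 in every library of these marks.

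The calls of different marks met at the same genes. Genes with shDDX6-only H3K27ac had shCTRL-only H3K27me3 in 418 cases against 129 expected of independent lists (adjusted p = 2.38e-117), among them MVB12B, UNCX, MAN1A1 and SDC2. Genes with shDDX6-only H3K4me3 had shCTRL-only H3K9me3 in 332 cases against 66.0 expected (adjusted p = 1.85e-150), such as OTP, SCN3B, CHST2 and SLC35F1. The active marks were shDDX6-only together at 274 genes against 90.3 expected, with XKR6, DAB2 and FZD6 first, and shCTRL-only together at 42 against 2.83, with KDM6A, CDKN2A, ZNF382, ZNF529 and ACSL5 first. Shared shDDX6-only H3K27me3 and shCTRL-only H3K9me3 was found at 130 genes against 33.2 expected, GUCY1B1, SOX8, SP5 and PAX6 among them. Of the 24 tests 15 passed, 12 above and 3 below the expected overlap. Which lists share a control is not known, so overlap across marks is not free of it. Expected counts and p, here and below, took all genes as open to each call. Overlap of the genes open to both calls, and peaks shared by neighbours, can thus account for part of an excess or deficit. How much was not tested.

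Active and repressive marks also met in the same direction. Genes with shDDX6-only H3K4me3 had shDDX6-only H3K27me3 in 134 cases against 42.5 expected (log2 odds ratio 2.01, adjusted p = 3.18e-33), MSX1 among them, and shCTRL-only H3K27me3 in 204 against 120.4 (log2 odds ratio 0.95). The order of these 2 overlaps turned at equal covered length, with log2 odds ratios of 0.95 and 2.07, and with a −log10 q of at least 3 (1.60 and 1.86). Genes with shDDX6-only H3K27ac had shCTRL-only H3K9me3 in 209 cases against 70.5 expected. Below the expected overlap were shCTRL-only H3K27ac with shDDX6-only H3K4me3 (0 against 14.6), and shDDX6-only H3K27ac with shDDX6-only H3K27me3 (18 against 45.5) or shCTRL-only H3K4me3 (7 against 17.4). The last passed in 3 of 9 other settings, with an adjusted p of up to 0.754. A further 3 calls passed in 7 of 9 settings each: shDDX6-only H3K27ac with shDDX6-only H3K27me3, ended with a −log10 q of at least 3 (0.144) and without shDDX6 replicate 1 (0.208), shDDX6-only H3K27me3 with shDDX6-only H3K9me3 (13 against 5.08), ended with a −log10 q of at least 3 (1) and an equal number of peaks (0.159), and shCTRL-only H3K27me3 with shCTRL-only H3K9me3 (169 against 94.1), ended with a −log10 q of at least 3 (0.315) and at equal covered length (0.111). Shared shCTRL-only H3K27ac and shDDX6-only H3K27me3, at PROK2, CA8 and 18 other genes (20 against 7.37 expected), turned to 9 against 19.5 with a −log10 q of at least 3 and ended at equal covered length (28 against 26.7, adjusted p = 0.872). Shared shCTRL-only H3K27ac and shDDX6-only H3K9me3 (5 against 1.75, adjusted p = 0.0499) passed in 0 of 9 other settings.

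Active genes numbered 9120 in the shCTRL-labelled and 10143 in the shDDX6-labelled libraries, with 8452 in both. Bivalent genes numbered 1334 and 1145, with 367 in both, and 554 genes bivalent in the shCTRL-labelled libraries were active in the others. H3K27me3 alone marked 2364 and 1296 genes, 776 of them in both, and 409 of the former were bivalent in the shDDX6-labelled libraries. H3K9me3 alone marked 867 and 315 genes, 229 in both. These counts carry no test. The direction for active genes turned with a −log10 q of at least 3 (7065 in the shCTRL-labelled and 5735 in the shDDX6-labelled libraries), an equal number of peaks (9046 and 8823) and equal covered length (8754 and 7876), and for bivalent genes at equal covered length (665 and 967).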

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

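All tests of explanations here, except those on missing DNA and on H3K27me3 list length, were chosen after the results were seen. Peaks outside the assembled chromosomes were in every mark and entered no comparison, which is what brought them here. The shDDX6- and shCTRL-labelled lists held 141 and 128 such peaks for H3K27ac, 278 and 278 for H3K4me3, 372 and 351 for H3K27me3, and 1053 and 1348 for H3K9me3.

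The empty segments around CDKN2A and KDM6A fitted missing DNA in the cells behind the shDDX6-labelled libraries. Of genes with H3K27ac and H3K4me3 in both shCTRL-labelled libraries of each mark outside the segments, 0.199% had no peak of any mark in the shDDX6-labelled libraries, so loss of every mark was rare elsewhere; genes inside are empty by the way the segments were found and add nothing. Scaled by the total peak numbers of the lists, the 227 shCTRL-labelled peaks there correspond to 242 shDDX6-labelled ones. The shDDX6-labelled lists as wholes, weighted by the marks found there, were thus not poorer in peaks. The segments were chosen for being empty, so the 0 found there adds nothing to this. A deletion within the labelled line and nothing else would have left every library checked matching its labels. At loci not reported, 6 of 12 did not match. That mismatch bears on the origin of the cells, and a deletion could still give the empty segments. Loss of marks with the DNA kept cannot be told apart from peaks alone, because the 227 shCTRL-labelled peaks have no read values beside them here. The groups may thus differ in the origin of their cells as well as in the hairpin, and which group departs from its labels is left open.

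The excess of H3K27ac calls in the shDDX6-labelled libraries went with longer lists, and the share of shDDX6-only genes was 45% at equal covered length. Equal length removes a genome-wide gain as fully as a difference in depth, so this cannot tell whether list length is a technical source. The knockdown could not be judged as its source from the 86.1% with the lists as deposited, because hairpin and cells may differ together.

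The H3K27me3 difference did not come from list length, since its Jaccard index was still 0.461 higher within than between groups at equal covered length. Group differences over 1 Mb bins correlated between marks at −0.139 at most in size, so no broad shift common to the marks was seen. A shared control could act at single peaks, and which lists share one is not known, so this cannot exclude it. Different cells behind the groups could give the correlation of 0.994 between the differences of the same-number libraries, but so could the knockdown, and the test cannot tell.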

How the results depend on the processing

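Leaving out each library, equal lists, stricter peaks and other windows were planned before the data were examined. The H3K4me3-richer gene end, the crossed block, the tail statistic of the shift test and the counts without genes in the 2 empty segments were chosen after seeing the data. The last moved no count by over 1.5 times, and the window at the 5′ end was not run for want of strand. The empty segments divide the libraries by whole arms, so no count could be made without either set. The group similarity kept its call in 9 of 9 alternatives (0.182 to 0.285), the calls across marks numbered 13 to 17, and each set of 10 named genes kept at least 7 members in every setting, or for H3K9me3 at least 3 (shDDX6-only) and 5 (shCTRL-only). Depth per list is unknown and limits every count. For each change below the cause was not tested, unless the list was shortened by construction.

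With a −log10 q of at least 3, shDDX6-only and shCTRL-only gene ends were 474 and 853 for H3K27ac and 65 and 512 for H3K9me3. Regions were 1228 and 1618 for H3K27ac, 4510 and 7805 for H3K27me3, 3185 and 3408 for H3K9me3, and 1682 shCTRL-only for H3K4me3. H3K27me3 list calls were 2, active genes 7065 (shCTRL) and 5735 (shDDX6), and bivalent genes 878 (shCTRL) and 522 (shDDX6). The overlap of shCTRL-only H3K27ac with shDDX6-only H3K27me3 turned to 9 against 19.5 expected.

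With an equal number of peaks, H3K27ac gene ends were 808 and 562, and H3K27ac regions 4258 and 5710. At equal covered length, gene ends were 599 and 732 for H3K27ac, 2179 and 87 for H3K4me3 and 652 shCTRL-only for H3K9me3. Regions were 2494 and 5350 for H3K27ac, 5367 and 96 for H3K4me3, 18959 and 13479 for H3K27me3, and 6874 and 5079 for H3K9me3, with 665 (shCTRL) and 967 (shDDX6) bivalent genes.

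With 5 kb bins, regions were 3779 and 1850 for H3K27ac, 2745 and 4259 for H3K9me3, and 951 and 2974 for H3K4me3. With at least a fraction of 0.5 of the window covered, gene ends were 464 shCTRL-only for H3K27ac and 59 and 596 for H3K9me3. With 2.5 kb windows, shDDX6-only H3K9me3 gene ends were 240. Of shDDX6-only against shCTRL-only calls, list calls were 0 for H3K27ac, 1 for H3K4me3, 0 for H3K27me3 and 0 for H3K9me3.

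Limma without a block gave 1160 higher and 3386 lower genes for H3K27me3, 1933 and 2546 for H3K4me3, and 320 and 1227 for H3K9me3 (adjusted p under 0.05). With the replicate block it gave 2514 and 369 for H3K27ac, 1071 and 3171 for H3K27me3, and 1526 and 906 for H3K4me3. The labels do not say that equal replicate numbers pair, and replicate differences correlated across groups at −0.324 to 0.147 over 1 Mb bins. With the crossed block the counts were 2404 and 357 for H3K27ac, 1070 and 3174 for H3K27me3, 1735 and 1325 for H3K4me3, and 297 and 1199 for H3K9me3. All these limma counts are descriptive, given its excess of false calls in the simulation.

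Leaving out 1 library gave gene ends of 1505 to 2361 (shDDX6-only) and 248 to 569 (shCTRL-only) for H3K27ac and 196 to 651 (shDDX6-only) for H3K9me3. Regions were 14056 to 41827 and 5320 to 14916 for H3K27ac, 4864 to 8874 and 3355 to 6335 for H3K4me3, 19398 to 31203 and 22707 to 35634 for H3K27me3, and 9374 to 29592 and 12579 to 27195 for H3K9me3. List calls were 4 to 8 for H3K27ac and 2 to 5 for H3K9me3. The largest shDDX6-only values came without shDDX6 replicate 1 for H3K27ac and without shDDX6 replicate 2 for H3K9me3. The balance of regions turned without shCTRL replicate 2 for H3K27ac, without either shCTRL replicate for H3K4me3, without either shDDX6 replicate for H3K27me3 and without shDDX6 replicate 2 for H3K9me3. A left-out library leaves 1 in its group, so a call then needs fewer libraries.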

Other observations

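Some genes with H3K27ac and H3K4me3 in both libraries of a group, here with or without H3K27me3, held no mark at all in the other. Of 10500 such genes in the shDDX6-labelled libraries, 80 had no peak of any mark in the shCTRL-labelled ones, among them the class II genes CD74 and HLA-DRB1, the integrin ITGAX, the formyl peptide receptor FPR1, RUNX3 and JAK3. Outside the empty segments 19 of 9548 genes showed the reverse, among them LCK, CD69, PRG2, FHIT and ACSL5. These names were chosen after their values were seen, and no test was made of the 2 counts.

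HOXA9 held both active marks in all 8 libraries of these marks. CD34, a stem cell marker, had H3K27me3 in the shDDX6-labelled libraries alone (fold 3.33 and 3.19).

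As a hypothesis, absence of the H3K27me3 demethylase KDM6A would raise H3K27me3, but covered length was lower in both shDDX6-labelled libraries (log2 ratio −0.13), and since length also depends on depth the test, written after the lengths were seen, cannot tell.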
